A study of Drosophila melanogaster with 8 samples.

How the data were processed

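The series holds 8 arrays of Drosophila S2 cells, 2 for each of 4 groups: total RNA and ribosome-bound RNA of cells treated with double-stranded RNA against GFP (control) or against DENR. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was prepared by the Affymetrix protocol. The deposited values are log2 signals per probe set made with RMA, per the submitters' processing notes, which give no version or settings. RMA in general corrects the background, brings the arrays to one distribution of probe signals and summarises the probes of a set; a change of most transcripts in one direction is therefore removed from the values. Whether all 8 arrays were normalized together is not given in the sources used here. That the values are log2 was taken from their range, 0.83 to 12.88. The array medians ran from 2.32 to 2.48. No detection calls or scanner signals were used here, so that genes near background were recognised only by their level, and the number of arrays limits the precision.

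Of 18952 probe sets, 183 control probe sets were left out. Of the other 18769, 13647 had 1 gene symbol, 402 had several and 4720 had none in the table that pairs probe sets with genes. Symbols were checked by gene identifier against a RefSeq gene table of the Release 6 assembly, where 13544 probe sets matched. Probe sets with several or no symbols were tested but not named. For the 1094 genes with more than 1 probe set, the one with the highest mean over all 8 arrays was used. Of 17104 features, the brightest 60% by mean log2 signal were kept, which left 10262 features with a mean of at least 2.12, among them 8164 named genes. Because no genome or annotation of transcripts was used here, no coordinates are given and the planned comparison of genes with and without upstream open reading frames was not run.

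All comparisons came from 1 limma fit (limma 3.58.1, R 4.3.3) of 4 group means to all 8 arrays, without covariates. The contrasts were knockdown minus control in total RNA, knockdown minus control in ribosome-bound RNA, the difference between these (ribosome loading, an interaction term) and ribosome-bound minus total RNA in control cells. Empirical Bayes moderation joined 4 residual degrees of freedom to a prior of 5.93, p-values were two-sided, and features were called at a Benjamini-Hochberg adjusted p under 0.05. Errors beside log2 fold changes are moderated standard errors. Gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists with at least 5 tested members in each comparison. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, whereas fry asks whether a list moves, on balance, one way.

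The genes named in the report were chosen by a rule fixed before the data were examined. It took DENR, MCTS1, eIF2D, InR and EcR; in each knockdown comparison the 8 named genes with the largest rise and the 8 with the largest fall among called genes whose arrays did not overlap; where none was called, the 4 of smallest p in each direction, given as values; up to 4 called members of each fixed list; and the 5 most enriched and 5 most depleted genes in control cells. In control cells, members are named in the report only for lists called by camera. Genes outside this rule are named only in the closing section, where they were chosen after their values were seen.

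The scripts were tested on simulated data with the means and spread of these arrays, in which 200 of 10262 genes were changed. Of genes changed by log2 1, 97.0% were recovered in total RNA, 96.0% in ribosome-bound RNA, 71.5% in ribosome loading and 96.5% in control cells. At log2 2 these shares were 100%, 100%, 99.0% and 100%. Alternatives were a replicate block, the culture as a random block, no filter or a stricter one (the brightest 40%), all probe sets, other normalizations (medians centred, quantile normalization within each fraction, cyclic loess), an intensity trend with a robust prior, a minimum of 1.5-fold, only the arrays compared, and each array left out in turn. A crossed replicate block and a minimum mean log2 signal of 5 were added after seeing the data. Figures were drawn with matplotlib 3.10.9.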

Results

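Transcript levels were measured in S2 cells, a Drosophila melanogaster line derived from embryonic haemocytes, the blood cells of the fly. The cells had been treated with double-stranded RNA against DENR or, as a control, with double-stranded RNA against GFP, which has no target in the fly genome. DENR forms a complex with MCTS1 that acts in the re-initiation of translation after short upstream open reading frames. From each treatment, total RNA and the RNA bound to ribosomes (the fractions holding single ribosomes and polysomes) were hybridised to oligonucleotide arrays. The 4 groups were control total RNA, DENR knockdown total RNA, control ribosome-bound RNA and DENR knockdown ribosome-bound RNA, with 2 arrays in each. The array signal was on the log2 scale and ran from 0.83 to 12.88, with array medians between 2.32 and 2.48. The number of arrays limits the precision of every value. The design text calls the 2 samples of a group biological replicates. Standard errors (SE) and p-values rest on the spread within groups, pooled over all 4 groups and moderated across genes. They therefore do not measure the spread of the 2 groups compared alone.

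The DENR transcript itself was examined first. In ribosome-bound RNA, DENR fell by 3.40 ± 0.25 on the log2 scale (SE, n = 2 per group), a 10.6-fold decrease, with adjusted p = 0.000203 by limma with Benjamini-Hochberg adjustment. Its log2 signal was 8.41 and 8.26 on the control arrays and 5.40 and 4.46 on the knockdown arrays. In total RNA, the control arrays read 8.28 and 8.18 and the knockdown arrays 7.38 and 7.60. This difference of -0.74 ± 0.25 did not pass the limma test after Benjamini-Hochberg adjustment (adjusted p = 0.170, and 0.0541 to 0.539 over the alternatives), although both knockdown arrays lay below both control arrays. MCTS1, the partner of DENR, differed by -0.02 ± 0.16 in total RNA and -0.29 ± 0.16 in ribosome-bound RNA, neither past the test. eIF2D, a related initiation factor, differed by -0.16 ± 0.14 and 0.17 ± 0.14, also without a call. All 3 genes have 1 probe set each on the array.

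**Figure D1:**
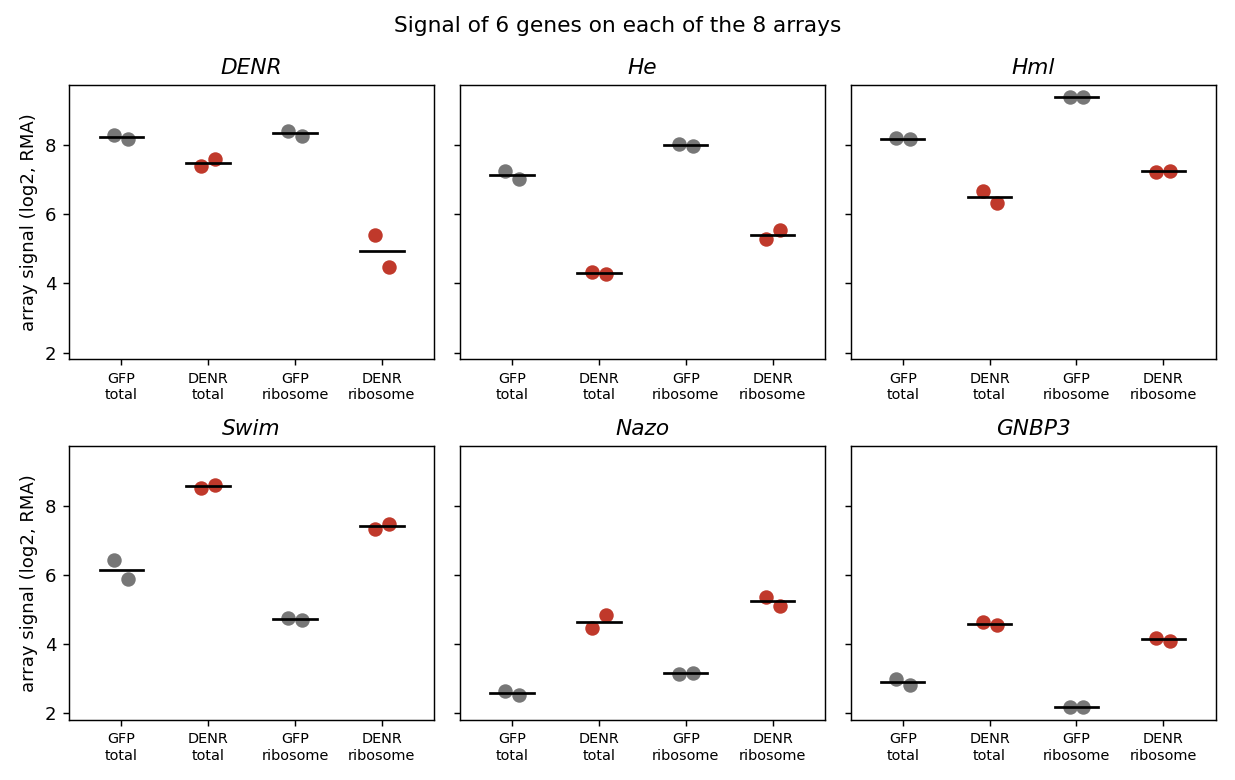
Array signal (log2, vertical axis) of DENR, He, Hml, Swim, Nazo and GNBP3 on each of the 8 arrays, by treatment and RNA fraction; points are single arrays and lines are means of the 2 arrays of a group. He and Hml lie lower, and Swim, Nazo and GNBP3 higher, on both knockdown arrays of either fraction, whereas DENR reads 7.38 and 7.60 in knockdown total RNA but 5.40 and 4.46 in knockdown ribosome-bound RNA.

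The comparison of total RNA asked which mRNA levels changed on DENR knockdown. The largest fall was that of He, a haemocyte surface protein, which fell by 2.85 ± 0.14 on the log2 scale (SE, n = 2 per group), a 7.19-fold decrease. NimB3 and NimB4, of the Nimrod family of EGF-repeat proteins, fell by 1.86 ± 0.13 and 1.76 ± 0.17, next to firl (-1.85 ± 0.16), Fa2h, a fatty acid hydroxylase (-1.74 ± 0.17), CG14273 (-1.71 ± 0.17), Hml, a clotting protein of haemocytes (-1.69 ± 0.14), and wun2, a lipid phosphate phosphatase (-1.60 ± 0.13). The largest rises were those of Swim, a secreted protein that binds Wingless (5.32-fold, 2.41 ± 0.18), and Nazo, an antiviral gene (4.16-fold, 2.06 ± 0.16). Pask, the PAS-domain kinase (1.73 ± 0.16), GNBP3, a recognition protein for fungal glucans (1.68 ± 0.13), CG31997 (1.64 ± 0.13), CHKov2 (1.59 ± 0.28), Cyp4d1, a cytochrome P450 (1.52 ± 0.18), and CG10834 (2.83-fold) followed.

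Of 10262 features tested in total RNA, 90 rose and 72 fell at an adjusted p under 0.05 by limma with Benjamini-Hochberg adjustment. The arrays of both groups did not overlap for 46.0% of features, against 33.3% by chance. The balance of rises and falls turned with other scalings, to 106 and 116 with quantile normalization within each fraction and 88 and 105 with cyclic loess, and was 391 and 106 without the second knockdown total RNA array. The count of 162 rested on single arrays. It was 105 and 39 without the first and the second control total RNA array, 61 and 497 without the first and the second knockdown total RNA array, 102 without either control ribosome-bound array and 97 without either knockdown ribosome-bound array. It was 46 with only the arrays compared and 105 with array medians centred. Of 25 named genes called in this comparison, 19 were also called without any single array, and CHKov2, CysRS-m, Rel, ATPsynepsilonL, PPO3 and LManI lost the call without at least 1 array. Rel, PPO3 and LManI also lost it with array medians centred, Rel and PPO3 with the replicate block, and Rel with the culture as a random block and with cyclic loess.

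Of the 16 plasmatocyte and haemocyte markers tested in total RNA, 4 fell, 0 rose and 12 did not pass the test, and the same 4 fell when adjusted over the list alone. The 4 were He, Hml, the scavenger receptor Sr-CI (-1.45 ± 0.18) and the phagocytosis receptor NimC1 (-1.21 ± 0.16). The list lay lower than other genes by camera with a preset correlation (median -0.18, adjusted p = 0.000236), but not with an estimated correlation (adjusted p = 0.694 with an estimated correlation). Mitochondrial ribosomal proteins (71 tested, median -0.15, adjusted p = 0.00122) and cytoplasmic ribosomal proteins (38 tested, median -0.09, adjusted p = 0.00633) also lay lower by camera, and no single member of either passed the test, over all genes or adjusted over the list alone. Germline markers (8 tested, median 0.44, adjusted p = 0.00633), cell cycle and DNA replication genes (28 tested, median 0.26, adjusted p = 0.0190) and protein kinases (50 tested, median 0.14, adjusted p = 0.0194) lay higher. No member of these passed over all genes, and 4 germline markers, 3 cell cycle genes and 2 kinases rose when adjusted over the list alone. None of the 6 lists held with an estimated correlation (smallest adjusted p = 0.694 with an estimated correlation), and fry called 0 lists. With the stricter filter the calls of the cell cycle genes, kinases and germline markers ended. With cyclic loess those of the cell cycle genes, kinases and cytoplasmic ribosomal proteins ended, the last with a median of 0.04. Quantile normalization within each fraction ended those of the kinases and the cytoplasmic ribosomal proteins.

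The first knockdown total RNA array stood apart from its mate. It lay towards the ribosome-bound arrays, at -9.0 on a first principal component holding 65.8% of the variance, against -27.3 for the second array and -29.6 and -35.1 for the control total RNA arrays. Without it, camera called only 2 lists in total RNA, the haemocyte markers (median -0.37, adjusted p = 7.89e-10) and the cytoplasmic ribosomal proteins (median -0.06, adjusted p = 0.0237). The mitochondrial ribosomal proteins (median -0.04), germline markers (0.34), cell cycle genes (0.15) and kinases (0.06) then had adjusted p = 0.217, 0.0566, 0.217 and 0.629. The size of the shift of the haemocyte list, though not its call, also depended on single arrays. Its median was -0.05 without the second knockdown total RNA array and -0.05 without the first control total RNA array. Without the second control total RNA array camera called 3 lists, and the calls of the cytoplasmic ribosomal proteins, cell cycle genes and kinases ended (adjusted p = 0.0695, 0.320 and 0.106).

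Single members of other fixed lists also changed in total RNA. Among 13 JAK-STAT and immune effector genes, 2 rose: AttD, an attacin (1.38 ± 0.17), and the NF-kappaB factor Rel (0.76 ± 0.16), which was also the 1 of 54 transcription factors called. Adjusted over the list alone, 3 immune effector genes rose and 1 fell. ImpE3 (1.24 ± 0.15) was the 1 of 10 ecdysone signalling genes called, CysRS-m (0.93 ± 0.16) the 1 of 30 aminoacyl-tRNA synthetases and ATPsynepsilonL (0.77 ± 0.13) the 1 of 65 oxidative phosphorylation genes. PPO3, a prophenoloxidase of lamellocytes, fell by 0.70 ± 0.14, and LManI, a lysosomal mannosidase on the list of fat body, gut and follicle cell markers, fell by 1.17 ± 0.21. InR and EcR, the insulin and ecdysone receptors, differed by -0.26 ± 0.14 and -0.12 ± 0.27, without a call. Neuronal markers (7 tested) had 0 calls, and muscle markers (3 tested) had 0.

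The comparison of ribosome-bound RNA asked which transcripts became more or less abundant on ribosomes. After DENR, the largest falls were those of He (6.02-fold, -2.59 ± 0.14 on the log2 scale, SE, n = 2 per group) and Hml (4.40-fold, -2.14 ± 0.14). NimB5 fell by 1.52 ± 0.13, and so did path, an amino acid transporter (-1.53 ± 0.25), Ac78C, an adenylyl cyclase (-1.68 ± 0.29), and Hers, a regulator of histone genes (2.84-fold lower). Nf1, a Ras GTPase-activating protein, fell by 1.73 ± 0.14 on its brightest probe set, while its other probe sets read -0.47 and -0.26. Swim rose 6.40-fold (2.68 ± 0.18), Nazo 4.21-fold (2.07 ± 0.16), GNBP3 3.89-fold (1.96 ± 0.13) and CG10834 3.79-fold (1.92 ± 0.15). Cyp4d1 (1.67 ± 0.18), CG7142 (1.62 ± 0.21), grk, a TGF-alpha-like ligand (1.57 ± 0.16), and CG33468 (1.55 ± 0.19) completed the largest rises. The control level of GNBP3 on ribosomes (2.18) lay below the array medians and near the filter level of 2.12, and that of AttD was 2.44 in total RNA, so their folds are lower bounds where these levels are background.

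In ribosome-bound RNA, 67 features rose and 71 fell by limma with Benjamini-Hochberg adjustment. Without the first and the second control ribosome-bound array the count of 138 became 36 and 28, without the first and the second knockdown ribosome-bound array 23 and 30, and without either knockdown total RNA array 212. It was 395 with only the arrays compared, 224 with an intensity trend and robust prior, and 81 with array medians centred. Apart from DENR, 12 of 23 named genes were called without any single array. Ac78C, AttD, CG33468, CG7142, chico, Dyrk2, Hers, LManI, NimC1, path and Sr-CI lost the call without at least 1 array. With array medians centred, Ac78C, path, Hers, chico, Dyrk2 and Sr-CI lost it too.

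Of the 16 haemocyte markers, 4 fell in ribosome-bound RNA: He, Hml, NimC1 (-1.22 ± 0.16) and Sr-CI (-1.09 ± 0.18). Adjusted over the list alone, 9 fell. The list had a median of -0.59 and adjusted p = 5.89e-11 by camera, adjusted p = 0.314 with an estimated correlation, and fry also called it lower (adjusted p = 0.0368). The JAK-STAT and immune effector genes lay higher (13 tested, median 0.17, adjusted p = 0.0131 by camera; adjusted p = 0.314 with an estimated correlation; adjusted p = 0.0104 by fry). Of these AttD rose (1.38 ± 0.17), 12 did not pass, and 3 rose when adjusted over the list alone. The call of this list ended with the stricter filter (adjusted p = 0.0698) and with a mean log2 of at least 5 (adjusted p = 0.0654), and its median ran from 0.10 without the first to 0.31 without the second knockdown ribosome-bound array. ATF4 and integrated stress response genes (14 tested, median -0.20, adjusted p = 0.0245), transcription factors (54 tested, median -0.12, adjusted p = 0.0131), the proteasome (32 tested, median -0.12, adjusted p = 0.0416) and cytoplasmic ribosomal proteins (38 tested, median -0.07, adjusted p = 0.0416) lay lower by camera with 0 members called over all genes. Adjusted over the list alone, 2, 5, 0 and 2 of their members fell. With an estimated correlation these lists had adjusted p = 0.314, 0.811, 0.811 and 0.884, in that order. Several of these calls rested on single arrays. The proteasome and the cytoplasmic ribosomal proteins lost the camera call without either control total RNA array (adjusted p = 0.0549 for both), without either knockdown total RNA array (adjusted p = 0.0664 for both) and without the first control ribosome-bound array (adjusted p = 0.0843 and 0.239). The proteasome also lost it without the second control or the first knockdown ribosome-bound array (adjusted p = 0.0594 and 0.180), and the cytoplasmic ribosomal proteins without the second knockdown ribosome-bound array (adjusted p = 0.528). The ATF4 list lost it without the first control ribosome-bound array (adjusted p = 0.0833) and the transcription factors without the second (adjusted p = 0.214). The calls of the proteasome and of the cytoplasmic ribosomal proteins ended as well with the culture as a random block, quantile normalization within each fraction and cyclic loess, the last 2 with medians of 0.03 and 0.02 for the ribosomal proteins.

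Among other fixed lists, chico, the insulin receptor substrate, fell in ribosome-bound RNA by 1.10 ± 0.22 and was the 1 of 12 insulin and TOR genes called, and the kinase Dyrk2 fell by 1.04 ± 0.20 and was the 1 of 50 kinases called. Both lost the call when any 1 of the 4 ribosome-bound arrays was left out, and Dyrk2 also without either control total RNA array. Both lost it with the culture as a random block and with medians centred, and chico with the replicate block. ImpE3 (1.52 ± 0.15) and ATPsynepsilonL (1.17 ± 0.13) rose, and LManI fell by 1.36 ± 0.21. InR differed by -0.22 ± 0.14 and EcR by 0.31 ± 0.27, without a call.

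The changes in the 2 fractions were then set against each other. Of the genes called in total RNA and in ribosome-bound RNA, 34 rose in both, among them Swim, Nazo, GNBP3 and AttD, and 29 fell in both, among them He, Hml, NimC1 and Sr-CI. Independent lists of these sizes would share 0.588 and 0.498. The fold changes of these comparisons come from different arrays, although arrays of both fractions may come from the same cultures. The calls are not independent, because both use the same spread for each gene, pooled over all groups. A gene of small spread is thus favoured in both lists. The numbers for independent lists are therefore no chance level for the 34 and 29. No gene was called in opposite directions. Across all tested genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.324 and Spearman rho = 0.183.

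**Figure D2:**
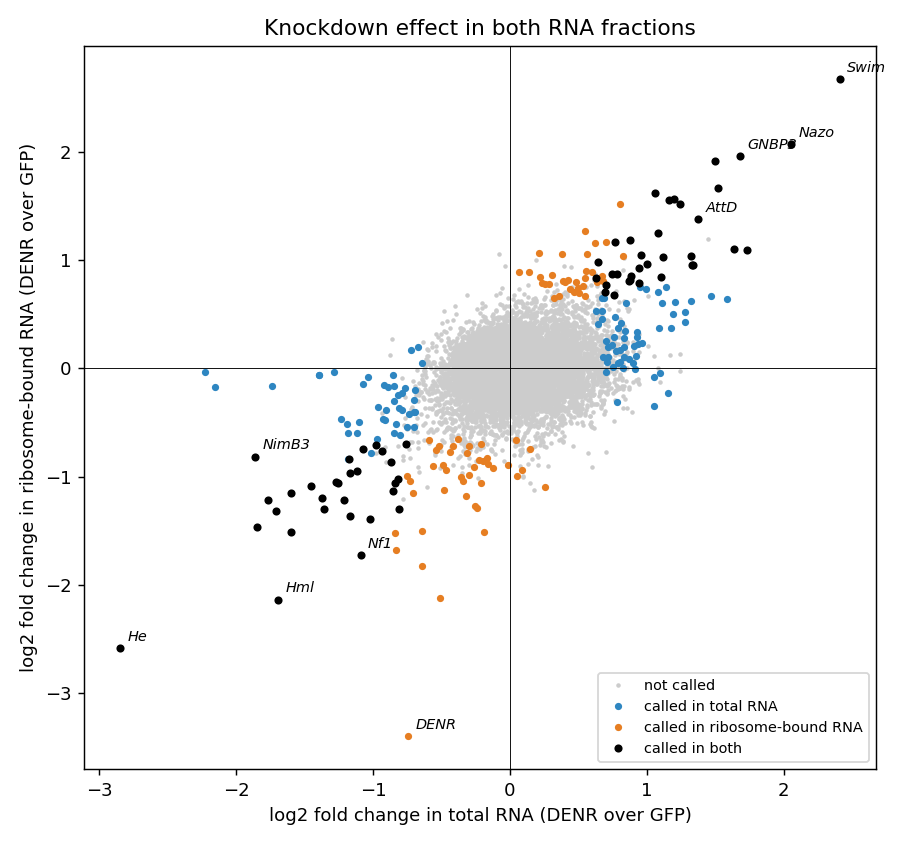
Log2 fold change on DENR knockdown in total RNA (horizontal axis) against that in ribosome-bound RNA (vertical axis) for the 10262 features tested; colours mark features called at an adjusted p under 0.05 in 1 fraction or in both. The 34 and 29 features called in both lie in the upper right and lower left, and DENR lies at -0.74 and -3.40.

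The comparison of ribosome loading took the change in ribosome-bound RNA beyond that in total RNA. It called 0 genes by limma with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05, 1022 features passed, 333 higher and 689 lower, where 513 would by chance. Of the other planned fits with all arrays, the replicate block and the fit without a filter each called 1, and the intensity trend with a robust prior called 3. DENR had a loading difference of -2.66 ± 0.35 (adjusted p = 0.101, and 0.00428 to 0.461 over the alternatives, of which 3 passed), and Wnk (-1.06 ± 0.20), Tsp3A (-1.03 ± 0.20) and shep (-0.87 ± 0.17) had the next smallest p among lower named genes. For shep, 3 other probe sets read between 0.05 and 0.80. The higher named genes of smallest p were CG15423 (1.26 ± 0.18), Fa2h (1.57 ± 0.24), CG12116 (1.33 ± 0.22) and NimB3 (1.04 ± 0.18). Fa2h read 5.42 and 3.68 in control and knockdown total RNA but 3.23 and 3.06 in ribosome-bound RNA, so its loading value came from total RNA. NimB3 likewise fell more in total RNA (-1.86) than in ribosome-bound RNA (-0.82), and CG15423 fell by 1.28 in total RNA. The loading of InR differed by 0.04 ± 0.20, of EcR by 0.43 ± 0.38, of MCTS1 by -0.27 ± 0.23 and of eIF2D by 0.33 ± 0.19. Without the second control total RNA array 1 feature was called higher, and without the first knockdown ribosome-bound array 1 was called lower. In data simulated on these arrays, the same fit recovered 71.5% of genes changed by log2 1 and 99.0% of those changed by log2 2 in ribosome loading. The simulated noise was independent between genes, without deviations shared by many genes of an array, so recovery in the real data may be lower.

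Gene lists shifted in ribosome loading by camera, with 0 single members called in any. Mitochondrial ribosomal proteins lay higher (71 tested, median 0.16, adjusted p = 0.00303). Lower were protein kinases (50 tested, median -0.18, adjusted p = 0.00458), transcription factors (54 tested, median -0.29, adjusted p = 0.0114), germline markers (8 tested, median -0.39, adjusted p = 0.0114), EGFR, Ras and MAPK signalling (11 tested, median -0.49, adjusted p = 0.0229) and cell cycle and DNA replication genes (28 tested, median -0.23, adjusted p = 0.0245). RNA interference genes (10 tested, median -0.47) and insulin and TOR signalling genes (12 tested, median -0.35) had adjusted p = 0.0388 each. Adjusted over the list alone, 1 insulin and TOR gene and 0 members of the other 7 lists were lower. All 8 lists had adjusted p = 0.658 with an estimated correlation, and fry called 0 lists. Without the first knockdown total RNA array, which lay towards the ribosome-bound arrays, camera called 0 lists in ribosome loading, with medians of 0.09, -0.10, -0.03, -0.34, -0.35, -0.12, -0.18 and -0.19 in the order given and adjusted p between 0.0971 and 0.349. With a mean log2 of at least 5, which left 5204 features, only the mitochondrial ribosomal proteins were called, while the medians of the EGFR list (-0.46), insulin and TOR genes (-0.43), transcription factors (-0.29), cell cycle genes (-0.27) and kinases (-0.16) stayed similar and that of the RNA interference genes was -0.07. With the stricter filter, the mitochondrial ribosomal proteins, transcription factors and germline markers were called. The insulin and TOR list and the RNA interference list lost the call with array medians centred (adjusted p = 0.0525 and 0.0622), quantile normalization within each fraction (adjusted p = 0.0698 and 0.138) and cyclic loess (adjusted p = 0.0737 and 0.0861), and the RNA interference list also with all probe sets (adjusted p = 0.0926). Cyclic loess ended the calls of the EGFR list and the cell cycle genes too (adjusted p = 0.0535 and 0.0635). Among the fits that left out 1 array, the insulin and TOR list kept its call only without the first control ribosome-bound array. Its median was -0.13 without the second control total RNA array. Camera called 4 lists without the second control total RNA array, 3 without the second control ribosome-bound array and 3 without the first knockdown ribosome-bound array.

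**Figure D3:**
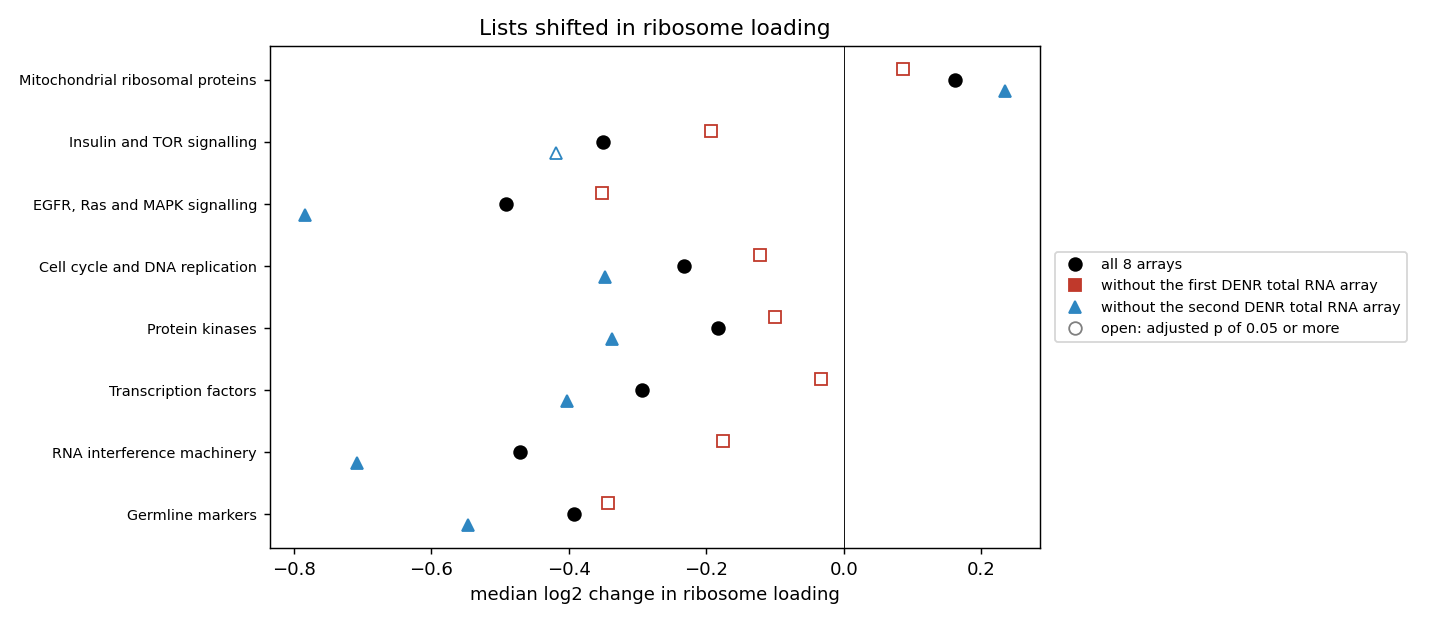
Median log2 change in ribosome loading (horizontal axis) of the 8 lists called by camera, over all 8 arrays and without the first or the second knockdown total RNA array; filled symbols have an adjusted p under 0.05. Without the first array every symbol is open and every median lies nearer to 0, the transcription factors at -0.03 against -0.29.

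The comparison of ribosome-bound with total RNA in control cells asked which transcripts were held on ribosomes to a larger or smaller degree before DENR was removed. The most enriched were Asx, a Polycomb-group gene (6.98-fold, 2.80 ± 0.17 on the log2 scale, SE, n = 2 per group), Ank, an ankyrin (6.75-fold, 2.76 ± 0.16), CG31999 (6.73-fold), the initiation factor eIF5 (6.48-fold, 2.70 ± 0.17) and nudE, a regulator of dynein (6.44-fold). The most depleted were an 18S ribosomal RNA pseudogene, 18SrRNA-Psi:CR41602 (8.20-fold, -3.04 ± 0.24), DCP2, the mRNA decapping enzyme (8.03-fold), CG42674 (7.36-fold, -2.88 ± 0.22), the ubiquitin ligase HERC2 (5.64-fold, -2.49 ± 0.21) and CG6707 (5.46-fold, -2.45 ± 0.16). The other probe sets of CG42674 read 1.75 and -0.24, and the other probe set of Ank, at a mean signal of 1.26, read -0.17. MCTS1 was enriched (0.94 ± 0.16) and eIF2D depleted (-0.79 ± 0.14), while DENR differed by 0.10 ± 0.25, InR by -0.30 ± 0.14 and EcR by 0.49 ± 0.27.

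In control cells 1915 features were enriched on ribosomes and 1125 depleted by limma with Benjamini-Hochberg adjustment, and with each array centred on its median the split was 2039 and 711. The count of 3040 became 2026 without the second control total RNA array and 1672 without the second control ribosome-bound array.

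Of 10 RNA interference genes, 6 were enriched in control cells and 0 depleted, among them Dcr-2 (2.01 ± 0.19), Ars2 (2.08 ± 0.26), Fmr1 (1.86 ± 0.29) and Hen1 (1.14 ± 0.20), with adjusted p = 0.0132 for the list by camera. Of 8 germline markers, 4 were enriched: piwi (2.14 ± 0.21), krimp (1.80 ± 0.19), AGO3 (1.40 ± 0.24) and spn-E (1.02 ± 0.20), and the list had adjusted p = 0.0196. Transcription factors (16 enriched, 3 depleted, 35 not called, adjusted p = 0.0249) included Hr39 (2.24 ± 0.17), Atf6 (2.17 ± 0.14), crc, the fly ATF4 (1.78 ± 0.18), and srp (1.52 ± 0.19). Protein kinases (18 enriched, 5 depleted, 27 not called, adjusted p = 0.0311) included mnb (1.98 ± 0.23), Dyrk2 (1.59 ± 0.20) and tefu (1.33 ± 0.13), against Akt at -1.59 ± 0.20. Mitochondrial ribosomal proteins lay lower (7 enriched, 20 depleted, 44 not called, adjusted p = 0.0196), with mRpS29 at -0.98 ± 0.13 and mRpL22 at -0.81 ± 0.13 but mRpL33 at 1.25 ± 0.15 and mRpS7 at 0.86 ± 0.14. Adjusted over the list alone, the enriched and depleted members numbered 7 and 0, 4 and 0, 20 and 3, 19 and 6, and 9 and 21 in these 5 lists. All 5 had adjusted p = 0.909 with an estimated correlation, and fry called 2 other lists. Other probe sets of mnb (-0.18, -0.26 and -0.49), Fmr1 (-0.30) and Hr39 (0.44, 0.47 and 0.84) read lower than those named. In control total RNA, AGO3 (1.53), Hen1 (2.19) and nudE (2.47) lay at or under the level of the array medians, so their enrichment is a lower bound where these levels are background. Without the second control ribosome-bound array only the RNA interference list was called, and without the second control total RNA array the calls of the kinases and of the mitochondrial ribosomal proteins ended (adjusted p = 0.101 for both). Without the first control total RNA array that of the transcription factors ended (adjusted p = 0.0639). With the stricter filter or a mean log2 of at least 5 only the mitochondrial ribosomal proteins were called, and with cyclic loess the kinases and transcription factors were not. The kinases also lost the call with array medians centred (adjusted p = 0.0629) and with the culture as a random block (adjusted p = 0.0517), and their median of 0.32 was 0.19 without the second control total RNA array and 0.18 without the second control ribosome-bound array. Cytoplasmic ribosomal proteins had 2 members enriched, 1 depleted and 35 not called.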

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

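The tests in this part were chosen after the results were seen, except the test of shared probe sets. The lists themselves and the loading comparison were planned. By camera with a preset correlation, gene lists differed between total and ribosome-bound RNA in their response to DENR knockdown, by a test of that difference itself (the interaction): mitochondrial ribosomal proteins (median log2 0.161), insulin and TOR signalling (-0.3506), EGFR, Ras and MAPK signalling (-0.4908), cell cycle and DNA replication (-0.2318), protein kinases (-0.1831), transcription factors (-0.2929), RNA interference machinery (-0.4706) and germline markers (-0.3921). None of the 8 held with an estimated correlation (adjusted p = 0.658 with an estimated correlation for each), and fry called 0.

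The first explanation tested for these list shifts was the first knockdown total RNA array, which lay towards the ribosome-bound arrays. Without it 0 lists were called and the mean of the 7 lower medians went from -0.34 to -0.19, against -0.51 and 9 called lists without its mate, so this explanation fits. An effect of normalization on dim members stays open: the 111 bright members lay at -0.179 against all bright genes (the 55 dim members at -0.350), but only at -0.0697 and -0.0820 in the pairings with the second knockdown total RNA array. Among genes with a mean log2 of at least 5 the medians of 5 lower lists stayed between -0.157 and -0.456, and that of the RNA interference genes was -0.0744. The knockdown itself cannot be told apart from these. Members lay below all genes in every pairing of knockdown arrays, from -0.479 to -0.0971. Their lists were picked for lying lower in loading over these same arrays, which largely set this outcome in advance. That choice also enters the values of the bright and dim members. The pairings with the second total RNA array gave only -0.128 and -0.0971, and all pairings share the same control arrays. Every list called in control cells was also called in loading, with the opposite sign. In control cells the medians were 0.32 (kinases), 0.33 (transcription factors), 0.62 (RNA interference), 0.70 (germline) and -0.25 (mitochondrial ribosomal proteins). The control arrays enter both comparisons with opposite signs, so their deviations would move both.

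The DENR signal was far lower in ribosome-bound than in total RNA after knockdown. Control RNA mixed into the knockdown total RNA arrays would need a share of 55.6% (36.2% at 2 SE) and would limit any fall to -1.46 at 2 SE, yet 5 genes, among them He, NimB3 and firl, fell past this limit by more than 2 of their own SE, which argues against it. A first test of the mixture, the median change of 70 genes lower in ribosome-bound RNA (-0.64 observed, -0.37 predicted), differed by -0.28, missed its own bound of -0.3 and was replaced by this one after it was seen. Whether introduced double-stranded RNA was read on the total RNA arrays stays open. Of 183 control probe sets, 1 changed in total RNA, at -1.546 in knockdown against control. Its means were 4.70 in control total RNA, 3.15 in knockdown total RNA, 2.65 in control and 2.44 in knockdown ribosome-bound RNA. Its target is not given in the sources used here, so its values cannot decide the question. Remaining DENR transcript held off ribosomes (loading -2.661, not past the test) cannot be told apart from introduced RNA, because the arrays do not separate introduced from cellular RNA.

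He, NimC1 and NimB1 to NimB5 lie side by side in the genome, and all 7 fell in total RNA (6 of them in ribosome-bound RNA). Of the other Nimrod genes tested, NimC4 was also called lower in total RNA (-1.39) and NimA was not (-0.05). Of the nearest tested genes outside this family, wb was called lower in total RNA (-0.87). The rest ran from -0.69 (Cyp28a5) to 0.04 (CenG1A) and did not pass the test. In ribosome-bound RNA, Dyrk2 (-1.04), wb (-0.87) and bgm (-0.72) were called lower. Of the 7 probe sets, 0 carry the array maker's mark for sequence shared between genes. Probe sequences were not compared here, so probes that read several related genes are not excluded. All 7 genes stayed called lower in total RNA under each of 3 other scalings of the deposited values, so scaling at that level does not account for the falls. The RMA step itself was not redone here. Fewer cells of a haemocyte-like kind may remain: the 14 haemocyte markers outside the locus had a median of -0.1622 in total RNA and -0.52 in ribosome-bound RNA, with 2 called lower in each, and such cells need not express every marker. A change that follows the locus also stays open. In total RNA, 7 neighbouring pairs were called the same way, against 1.25 on average and 7 at most in 10000 reshuffled orders (permutation p = 0.0005). In ribosome-bound RNA there were 7, against 0.857 on average and 6 at most (permutation p = 0.0001, the smallest these draws can give). Of these pairs, 6 and 5 lie in this locus. The counts therefore mostly restate the falls for which it was picked, and do not show an effect on neighbours elsewhere. The other pair in total RNA was CG15423 with Sr-CI. In ribosome-bound RNA the others were Dyrk2 with wb, near this locus, and Polr3I with DENR, the knockdown target. The locus was picked because its genes fell. The knockdown is the difference the design names, and none of these open explanations was tested against it.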

How the results depend on the processing

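The fits with a crossed replicate block or a mean log2 of at least 5 were chosen after seeing the data. No called result reversed, and the DENR levels in total and ribosome-bound RNA kept their direction and side of the threshold in all alternatives. Uncalled differences near 0 took both signs: without 1 array MCTS1 ran from -0.17 to 0.12 and EcR from -0.46 to 0.22 in total RNA, and InR from -0.05 to 0.14 in loading. The median of the cytoplasmic ribosomal proteins, not called there, was above 0 with cyclic loess. With the replicate block (the arrays share only a number) the counts were 116, 95, 1 and 2792 in total RNA, ribosome-bound RNA, ribosome loading and control cells, against 162, 138, 0 and 3040; called lists stayed at 6, 6, 8 and 5. Same-numbered control and knockdown arrays deviated together within total (r = 0.38) and ribosome-bound RNA (0.27) but in opposite ways between the fractions (-0.20 and -0.31), and with a crossed block the counts were 903, 413, 6 and 3928. Medians centred gave 105 in total and 81 in ribosome-bound RNA, only the arrays compared 46 and 395, a mean of at least 5, which tests fewer genes, 85 and 90. The intensity trend with a robust prior gave 224 in ribosome-bound RNA and 3 in loading, and no filter 1 in loading. Leaving out 1 array gave 39 to 497, 23 to 212, 0 to 1 and 1672 to 3251 genes, and 2 to 8, 4 to 6, 0 to 9 and 1 to 5 lists; it leaves 1 array in a group, assumed to vary like the other groups. Called lists, in the same order, were 0, 0, 0 and 0 with an estimated correlation and 0, 2, 0 and 2 with fry. They were 3 in total RNA, 3 in loading and 1 in control cells with the stricter filter, 3, 4 and 3 with cyclic loess, 3, 1 and 1 with a mean of at least 5, and 8 in control cells without a filter. With a mean of at least 5 the germline list had too few members to be tested in any comparison. Except for fewer arrays or genes, the cause was not tested. None of the alternatives for upstream open reading frames was run, because no transcript sequences were used here, and DENR has no other probe set. The 2 arrays per group and signals near background limit small changes.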

Other observations

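The genes and families in this part were chosen after their values were seen, with gene families taken from symbol stems. Of 105 families, camera called 4 in total RNA, 2 in ribosome-bound RNA, 3 in ribosome loading and 1 in control cells. The 3 in loading were the mitochondrial ribosomal proteins (median 0.17), the Nimrod genes (0.38) and the Su(var) genes (-0.75). No member was called, and each family had adjusted p = 0.978 by camera with an estimated correlation. The higher Nimrod loading came from larger falls in total RNA than on ribosomes, as for NimB3 (-1.86 against -0.82) and NimC4 (-1.39 against -0.06). In control cells NimB1 (-0.65), NimB3 (-1.04), NimB4 (-0.84) and NimC4 (-1.19) were already depleted on ribosomes, while the other members were not called. The Nimrod genes (8 tested) had 7 members lower in total RNA (family adjusted p = 9.23e-14; adjusted p = 0.270 with an estimated correlation) and 5 in ribosome-bound RNA (adjusted p = 2.91e-08; adjusted p = 0.656 with an estimated correlation). In total RNA, NimB1 fell by 1.23, NimB2 by 1.27, NimB5 by 1.60 and NimC4 by 1.39, whereas NimA differed by -0.05; in ribosome-bound RNA NimC4 differed by -0.06. The Idgf genes, secreted chitinase-like proteins, lay lower in ribosome-bound RNA (5 tested, median -0.42, adjusted p = 0.00218; adjusted p = 0.997 with an estimated correlation), and of these Idgf2 fell by 0.94.

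Sting rose in total RNA (1.09 ± 0.20), next to Nazo, Rel and AttD, and differed by 0.37 ± 0.20 in ribosome-bound RNA, without a call. The 5 SMC genes of chromosome structure were all enriched on control ribosomes (median 1.43, adjusted p = 0.00747; adjusted p = 0.964 with an estimated correlation). Polr3I, whose span overlaps DENR in the gene table, fell by 0.72 ± 0.14 in ribosome-bound RNA and differed by -0.30 ± 0.14 in total RNA, without a call.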
